A study of Danio rerio with 10 samples.

How the data were processed

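Chromatin of zebrafish lateral rectus muscle was immunoprecipitated for H3K27Ac, H3K27me3 and H3K4me3 in control muscle and at 9 and 18 hours post-injury (hpi), which gave 9 libraries, 1 for each mark and time, and 1 input library was sequenced beside them. Per the labels' protocols, tissue of many fish was pooled for each time, and the chromatin was sonicated before precipitation. The design text names wild-type fish, while the growth protocol names wild-type and α-actin::EGFP fish. Which fish went into which pool is not given in the sources used here. Groups were taken from the sample labels. The input library was not used here.

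Per the submitters' processing notes, BWA, MACS2 2.1.0 and SICER 12.1 were used with the genome build danRer10; the notes as used here give no role or order, so which caller made which list and at which threshold is not given in the sources used here. For each library the authors deposited a list of called intervals, and for each mark a table of merged regions, each the union of overlapping intervals of the mark's 3 libraries. Intervals were called per library. They lie on a grid of 200 bp windows with gaps of at least 800 bp between them. The deposited values used here are signal: the average and the maximum tag pileup of a library over the bins of an interval or region, without a ratio to input. The authors' normalization between libraries is not given in the sources used here. In intervals of at most 100 bins of about 32 bp, the average multiplied by the number of bins was a whole number in 100% of the intervals of each library, within a tolerance of 0.0006 per bin, so the pileups carry no scaling factor other than a possible removal of tags to equal numbers. The authors also deposited columns of another kind, 0 or 1 for the presence of an interval of each library in a region, and gene names with distances to gene starts. The distances in the region tables run from the middle of the region. Column names were checked by setting regions whose bounds equal an interval's beside the interval lists: 100% of the averages were equal in the column of the same library and at most 0.516% in any other. The number of columns matched to no sample was 0. The number of tags per library is unknown, so no precision from depth can be given. No genome was used, and gene names and coordinates, printed counting from 1, are those of the files.

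The change of a region was log2((average at 9 or 18 hpi + 1)/(average in control + 1)), with a pseudocount of 1. It therefore understates the change of weak regions. Regions whose mean average over the 3 libraries of the mark lay below the 25th percentile of the table were left out of the counts of all regions, and a region was called higher or lower at 2-fold or more. A region was called back near control when its value at 18 hpi lay within 1.5-fold of control. The start region of a gene was the region of the mark with the smallest deposited distance to the gene's start, up to 5000 bp; 17141 genes had one for H3K27Ac, 17564 for H3K4me3 and 10078 for H3K27me3. A region can serve several genes. Start regions of genes and lists, and their comparison between marks, were not filtered on low values. With 1 library per group no test of a difference was possible, and no p-value or standard deviation is given. Intervals were compared by overlap of at least 1 bp. Exact (Clopper-Pearson) 95% binomial intervals of shares cover counting error only. Correlations across genes describe these libraries, with intervals from 1000 bootstrap draws of regions. For the control shared by both times, unchanged libraries were simulated 100 times, and the overlap of independent lists is n1 × n2 / N. The simulated noise was normally distributed, with a spread taken from the deposited changes between 18 and 9 hpi at like signal. All 3 libraries of a mark, control included, were given that spread. Normal noise holds few large deviations, so the simulated counts of 2-fold changes may be too low.

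The 22 gene lists were sarcomere and contraction, myogenic regulators, immediate early and stress transcription factors, inflammation and cytokine signalling, leukocytes, cell cycle and DNA replication, epithelial-mesenchymal transition and matrix, fibroblasts and tendon, endothelium, nerve and Schwann cells, erythrocytes, retina and epidermis, HOX genes, developmental transcription factors outside the HOX clusters, pluripotency factors, chromatin modifiers of these marks, fibroblast growth factor signalling, autophagy and lysosome, oxidative phosphorylation, ribosome biogenesis, Notch and Wnt signalling, and cytoskeleton remodelling and cell migration. The median log2 change over a list's distinct start regions was set beside 10000 random lists of the same size, matched on decile of mean signal, and its percentile describes these libraries; a list is said to stand apart below percentile 2.5 or above 97.5. Of 130 combinations of list, mark and time, 49 stood apart, where 6.5 would on average if each list were a random draw of genes. Neighbouring and co-regulated genes are not independent, so percentiles are too extreme by an unknown amount. Genes named are, for each mark and time, the 6 with the largest rise and the 6 with the largest fall of the start region among regions at or above the median (50th percentile) of mean signal, without placeholder names or microRNAs, and for each list up to 4 members with the largest absolute H3K27Ac change, with their values in the other marks. The lists, this rule, the thresholds and the alternatives were written before the data were examined, apart from the alternatives that are named as later choices. Placeholder names were left out by set prefixes, and sb:cb1058, also of clone form, stayed in because its prefix was not among them.

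The method was tested on simulated libraries with Poisson noise for region length divided by 200 bp. Simulated changes acted on the whole pileup, background included, so the shares called do not cover loss of a mark above background. Of 50 regions raised 3-fold, 100% were called in each mark, and of 50 lowered to 0.333, 98% for H3K27Ac, 98% for H3K4me3 and 94% for H3K27me3. Of unchanged regions, 0.045%, 0.029% and 0.0075% were called in H3K27Ac, H3K4me3 and H3K27me3. With noise taken from the deposited changes, the simulations of the shared control called on average 143 higher and 142 lower H3K27Ac regions, 15.6 and 15.8 for H3K4me3 and 0 and 0 for H3K27me3 at 9 hpi. Of 200 unchanged random lists, 6%, 8.5% and 4% stood apart in H3K27Ac, H3K4me3 and H3K27me3, against the 5% that the limits set. Alternatives were a pseudocount of 5, no filter on low values, centring of the log2 changes on their median, correction for a trend with mean signal (lowess, span 30%), the maximum in place of the average, regions with an interval whose maximum pileup was at or above the median of its library's list (the lists give no score or p-value to rank by), a limit of 1.25-fold for regions back near control, an overlap of 50%, a start distance of 1000 bp, and the highest-signal region of a gene. After the data were seen, the region covering the gene start and regions with an interval in both libraries of a contrast were added, as was centring for start regions changed in both H3K27Ac and H3K4me3. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.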

Results

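Histone H3 acetylated at lysine 27 (H3K27Ac), trimethylated at lysine 4 (H3K4me3) or trimethylated at lysine 27 (H3K27me3) was mapped by chromatin immunoprecipitation and sequencing in the lateral rectus, an eye muscle, of adult zebrafish. H3K27Ac marks active promoters and enhancers, H3K4me3 marks promoters, and H3K27me3 marks genes silenced by Polycomb proteins. Muscle was taken from uninjured fish (control) and at 9 and 18 hours post-injury (hpi), after part of the muscle had been cut out. Tissue was pooled from 119 fish for control, 192 for 9 hpi and 200 for 18 hpi. Each mark had 1 library per time, 9 in all, and 1 input library was not analysed here. The comparisons ask how the 3 marks changed between uninjured and injured muscle and whether a change seen at 9 hpi was still there at 18 hpi, as the title of the series names a transient reprogramming. With 1 library per mark and time, no difference below has a replicate check, and no spread between animals can be given. "Higher" and "lower" with a count, and "rose" and "fell", mean a change of at least 2-fold between 2 libraries. The number of sequenced tags per library is unknown.

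The authors called 35692 H3K27Ac intervals in control, 34393 at 9 hpi and 28964 at 18 hpi, which covered 106.1, 85.0 and 111.2 Mb of the danRer10 genome. H3K4me3 gave 17331, 17117 and 17586 intervals on 53.1, 55.1 and 51.9 Mb, and H3K27me3 gave 15593, 15031 and 14760 intervals on 111.2, 95.4 and 96.7 Mb. The share of intervals within 1000 bp of a gene start was 33.6%, 36.8% and 39.8% for H3K27Ac, 76.3%, 77.0% and 76.3% for H3K4me3 and 29.5%, 30.5% and 31.0% for H3K27me3. The median average pileup of an interval, the mean number of overlapping tags, was 15.5, 18.8 and 13.9 for H3K27Ac, 30.8, 28.8 and 31.7 for H3K4me3 and 9.06, 9.73 and 9.52 for H3K27me3.

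At 9 hpi, the median H3K27Ac change at gene starts lay below matched random lists for the contractile apparatus and myogenic regulators. It lay above them for leukocyte, inflammation and ribosome biogenesis genes. Most start regions of the myogenic, inflammation and ribosome biogenesis lists changed less than 2-fold. The start region of atp2a1l, a calcium pump of the sarcoplasmic reticulum (chromosome 12, 13203801 to 13210800), had an average pileup of 22.04 in control, 5.19 at 9 hpi and 3.57 at 18 hpi. At il1b, the gene of the cytokine interleukin-1 beta (chromosome 10, 45106401 to 45107600), the values were 1.46 in control, 11.6 at 9 hpi and 4.75 at 18 hpi. An interval was called there at 9 hpi only, and the mean signal of this region lay below the filter of the region counts that follow. Of 31189 H3K27Ac regions kept, 4238 were higher and 2658 were lower at 9 hpi, so 61.5% of the changed regions were higher. The median change over all kept regions was not 0: it was 0.23 on the log2 scale at 9 hpi and −0.16 at 18 hpi. After centring on that median, 2526 regions were higher and 4066 were lower, and 38.3% of the changed regions were higher, so the direction of the majority depended on the scaling. It also depended on the filter, without which 5402 regions were higher and 6003 lower. H3K27Ac changes of genes and lists are therefore given relative to the median of all kept regions, as relative log2 changes, while pileups are as deposited. The change at 9 hpi also moved with signal: the median log2 change as deposited went from −0.17 in the fifth of the kept regions with the lowest mean signal to 0.49 in the fifth with the highest. It was 0.37 in the 15681 regions that the authors' annotation puts at a promoter and −0.0076 in the 15508 others.

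**Figure D1:**
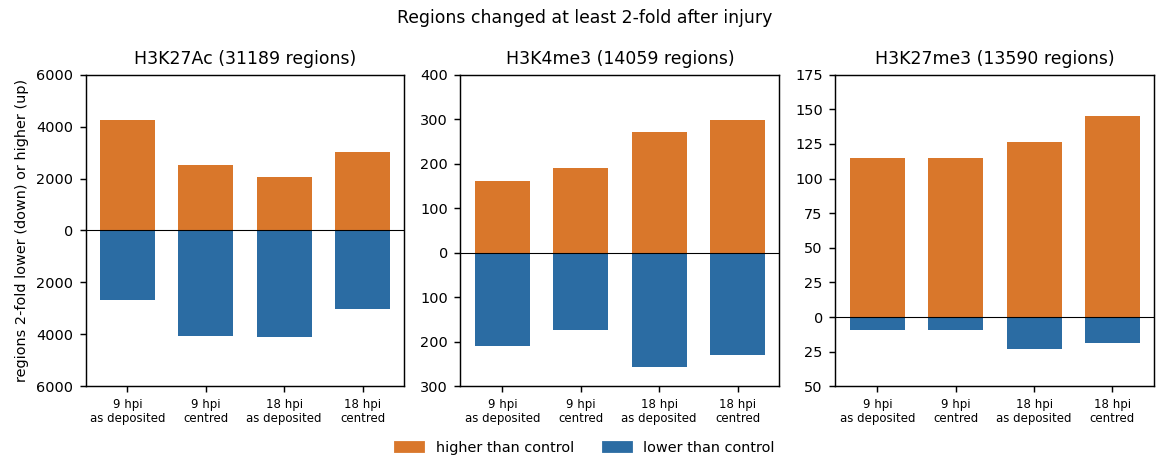
Number of regions at least 2-fold higher (bars above 0) or lower (bars below 0) than control, for 9 and 18 hpi, as deposited and after centring on the median of all kept regions, with a separate vertical scale for each mark. H3K27Ac had 4238 higher and 2658 lower regions at 9 hpi as deposited and 2526 and 4066 after centring, while no H3K4me3 or H3K27me3 count was above 297.

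Of the 50 measured start regions of the sarcomere and contraction list, 24 were lower, 1 was higher and 25 lay between at 9 hpi (28 lower after centring). The median relative log2 change of the list was −1.22, below all 10000 random lists matched on mean signal, whose central 95% ran from −0.39 to 0.19. The Z-disc gene ldb3b had an average pileup of 33.6 in control, 13.9 at 9 hpi and 5.91 at 18 hpi. The M-band gene myom1a had 16.4 in control, 6.12 at 9 hpi and 2.48 at 18 hpi, and jph2, whose product joins the sarcoplasmic reticulum to the cell membrane, had 22.6 in control, 9.02 at 9 hpi and 4.21 at 18 hpi. When each gene was represented by its region of highest signal and not by the one nearest its start, the list's median as deposited was −0.039, against −0.99, and still lay at the 0.02th percentile. Several members belong to families of near-identical genes, so tags of one copy may have been assigned to another. Of 23 start regions of myogenic regulators, 4 were lower and 0 higher (9 and 0 after centring), with a median relative log2 change of −0.80 (percentile 0.01). Among them, klhl31, a kelch-family gene of striated muscle, went from 22.05 to 6.24, and mef2aa from 8.405 to 1.9. The region nearest the start of myod1, the founding member of the myogenic factors, had 26.4, 13.2 and 7.24 in control, at 9 hpi and at 18 hpi, and its relative log2 change was −1.17 at 9 hpi and −1.58 at 18 hpi.

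Markers of other cell types moved in different directions beside the muscle genes. Of 30 leukocyte start regions, 15 were higher and 0 lower at 9 hpi (11 and 1 after centring), and the median relative log2 change of 0.74 lay at percentile 99.99. H3K27Ac upstream of spi1b, a transcription factor gene of myeloid cells, went from 1.69 in control to 11.5 at 9 hpi, where no interval was called. At spi1a it went from 8.02 to 28.05, and at fcer1gl, which encodes an Fc receptor chain, from 5.03 to 24.8. The antigen presentation gene cd74a went the other way, from 27.5 to 16.3 and then 9.13 at 18 hpi. The 10 erythrocyte start regions had a median of −1.06 (percentile 1.93), with 4 lower and 0 higher (7 and 0 after centring); with the highest-signal region of each gene this list was at percentile 26.6, and with regions within 1000 bp at 4.01. Fibroblast and tendon genes had a median of −0.88 over 9 regions (percentile 0.24, 3 lower and 1 higher): the collagen genes col6a2 and col6a3 went from 24.9 to 8.18 and from 22.99 to 9.42, while the tendon transcription factor gene scxa went from 3.77 to 10.9. With the highest-signal regions the median of this list as deposited was −0.10 at 9 hpi, against −0.65, at percentile 1.81. Endothelium (−0.06, percentile 48.5), nerve and Schwann cells (−0.44, percentile 5.13) and retina and epidermis (−0.35, percentile 22.01) lay inside the range of random lists. The nerve list had 4 higher and 4 lower of 13 start regions (1 and 4 after centring), and its median as deposited, −0.21, was 0.56 within 1000 bp and 0.57 with the highest-signal regions. Among its lower members, the myelin gene mbpa went from 23.9 to 6.02 and the synaptic gene snap25b from 16.3 to 4.27.

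Inflammation and cytokine genes had 9 higher and 2 lower of 46 start regions (6 and 3 after centring) and a median relative log2 change of 0.39 (percentile 99.8; 96.1 when regions had to lie within 1000 bp). Besides il1b, the cytokine gene il6 went from 2.13 to 14.2, il10 from 4.54 to 18.05 and the matrix protease gene mmp9 from 2.08 to 10.2. Like il1b, il6 and mmp9 had start regions whose mean signal lay below the filter of the counts of all regions. So did other genes named for H3K27Ac, among them mef2aa, zeb2b, cdc20, kif11 and alas2. Ribosome biogenesis genes had 18 higher and 1 lower of 67 (8 and 1 after centring) and a median of 0.46, above all random lists. Examples are utp20 (6.21 to 26.96), rrp9 (15.9 to 47.2) and the fibrillarin gene fbl (11.8 to 34.1). Cytoskeleton remodelling and cell migration genes had a median of 0.38 (percentile 97.8, 5 of 41 higher, 1 after centring), with the non-muscle myosin gene myh9a going from 5.87 to 23.95 and tuba1b, below 2-fold after centring, from 17.4 to 37.7. Under each of the 3 other ways to choose a gene's region this list fell inside the random range. Genes of epithelial-mesenchymal transition and matrix had a median of −0.51 (percentile 0.02, 8 of 39 lower, 3 higher, and 10 and 1 after centring). The hyaluronan synthase gene has2 went from 16.5 to 4.49 and the repressor gene zeb2b from 11.8 to 2.61, while the epithelial cadherin gene cdh1 went from 4.64 to 16.2. With the highest-signal regions this list was at percentile 8.9. Autophagy and lysosome genes had a median of 0.028, lower than matched lists (percentile 0.73), with 5 of 46 higher and 1 lower (2 and 1 after centring). The muscle atrophy ligase gene fbxo32 went from 28.1 to 11.9, and tfeb, a regulator of lysosome genes, from 4.19 to 12.6.

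The other lists lay inside the random range in H3K27Ac at 9 hpi. Their median relative log2 changes were 0.21 for immediate early and stress factors (percentile 30.2), −0.15 for cell cycle and DNA replication (percentile 2.54), −0.0021 for developmental transcription factors outside the HOX clusters (percentile 69.5), 0.43 for pluripotency factors (percentile 92.4), 0.28 for chromatin modifiers (percentile 69.2), −0.11 for fibroblast growth factor signalling (percentile 7.25), 0.19 for oxidative phosphorylation (percentile 3.58) and −0.028 for Notch and Wnt signalling (percentile 30.6). Single members changed within these lists. The AP-1 genes fosl1b and fosl2 went from 2.16 to 13.3 and from 44.1 to 105, the phosphatase gene dusp5 from 17.5 to 43.4 and cebpa from 23.6 to 60.2. The cyclin-dependent kinase gene cdk4 went from 11.6 to 30.1, while the mitotic genes cdc20 and kif11 went from 11.6 to 4.56 and from 11.8 to 5. The growth factor gene fgf2 went from 11.5 to 2.61 and fgf13a from 6.21 to 19.2. Of the HOX genes, hoxb4a alone had an H3K27Ac start region, so no list median was taken; it went from 11.5 to 27.02, below 2-fold after centring. With a pseudocount of 5, the H3K27Ac changes at 9 hpi of mef2aa, myom1a, jph2, col6a3, scxa, cdc20, kif11, fbxo32, tfeb, tuba1b and hoxb4a were below 2-fold. So was that of il1b at 18 hpi.

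Among all genes whose start region was at or above the median of mean signal, the limit for this and the later rankings, H3K27Ac at 9 hpi rose most at pigrl2.3 (chromosome 2, 51776001 to 51783600; 2.05 to 29.3), sb:cb1058 (chromosome 7, 24764201 to 24766400; 3.15 to 29.2), pglyrp5 (chromosome 18, 40914801 to 40916200; 3.96 to 34.7), c1ql3b (chromosome 2, 3766201 to 3767400; 2.65 to 24.6), mafbb (chromosome 11, 25143201 to 25146600; 10.5 to 75.7) and mthfd1l (chromosome 20, 26631801 to 26634200; 4.28 to 33.2), with average pileups in control and at 9 hpi. Their relative log2 changes ran from 2.47 for mthfd1l, a gene of mitochondrial folate metabolism, to 3.09 for pigrl2.3. The gene pglyrp5 encodes a peptidoglycan recognition protein and mafbb a transcription factor of the MAF family. The pigrl genes form a cluster of related immune receptor genes, so the assignment of tags to one copy is uncertain. The greatest falls were at ugt5d1 (chromosome 10, 25759801 to 25761000; 20.97 to 3.22), rnf207b (chromosome 23, 21586401 to 21589800; 27.8 to 6.04), rbp4 (chromosome 12, 5080601 to 5091800; 21.7 to 4.76), txlnba (chromosome 20, 36981201 to 36984800; 31.5 to 7.48), mbpa (chromosome 19, 22244601 to 22253400) and vstm4a (chromosome 13, 30819801 to 30822000; 22.6 to 5.68). Their relative log2 changes ran from −2.61 for the glucuronosyltransferase gene ugt5d1 to −2.05 for vstm4a; rbp4 encodes a retinol-binding protein.

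At 18 hpi, more start regions of contractile genes were lower in H3K27Ac than at 9 hpi, and the gain at immune genes was smaller. A lower share of muscle cells in the pooled tissue and less of the mark within them cannot be told apart here, for H3K27Ac or H3K4me3. Of the 50 sarcomere and contraction start regions, 36 were lower and 0 higher (34 lower after centring), with a median relative log2 change of −1.30, below all random lists. With the highest-signal regions its median as deposited was −0.66, against −1.46, still below all random lists. Myogenic regulators had 10 lower and 0 higher of 23 (8 and 0 after centring) and a median of −0.64 (percentile 0.09). Leukocyte genes had 2 higher and 1 lower (4 and 1 after centring) and a median of 0.41 (percentile 99.6); the percentile was 91.8 with regions within 1000 bp and 94.2 with the highest-signal regions. At spi1b the value reached 16.4, while spi1a was at 10.8, il6 at 4.37 and il1b at 4.75. Erythrocyte genes had 9 of 10 lower and a median of −1.33 (percentile 0.04): the heme synthesis gene alas2 went from 12.3 in control to 3.098 and the spectrin gene sptb from 24.1 to 6.33. This list was at percentile 43.1 with the highest-signal regions. Fibroblast and tendon genes had 6 of 9 lower, 1 higher (3 and 1 after centring) and a median of −0.94 (percentile 0.06). Epithelial-mesenchymal transition and matrix genes had 10 lower and 2 higher of 39 (5 and 2 after centring) and a median of −0.48 (percentile 0.04), and were at percentile 18.6 with the highest-signal regions. Oxidative phosphorylation genes had a median of −0.079 (percentile 0.83; 4.68 with the highest-signal regions) with 6 of 82 lower (4 after centring), among them cox5b2 (60.7 in control, 15.7 at 18 hpi), cox6a2 (33.9 and 10.5) and ppargc1a, a regulator of mitochondrial genes (17.8 and 5.25). Autophagy and lysosome genes had a median of −0.13 (percentile 1.55).

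The remaining lists lay inside the random range in H3K27Ac at 18 hpi, with median relative log2 changes of 0.065 for immediate early and stress factors (percentile 62.8), 0.10 for inflammation and cytokine signalling (percentile 85.97), 0.018 for cell cycle and DNA replication (percentile 65.7), −0.43 for endothelium (percentile 2.56), −0.20 for nerve and Schwann cells (percentile 24.8), −0.07 for retina and epidermis (percentile 49.01), 0.058 for developmental transcription factors outside the HOX clusters (percentile 74.4), 0.33 for pluripotency factors (percentile 93.03), 0.15 for chromatin modifiers (percentile 94.8), −0.09 for fibroblast growth factor signalling (percentile 22.1), 0.10 for ribosome biogenesis (percentile 85.96), 0.12 for Notch and Wnt signalling (percentile 87.2) and 0.17 for cytoskeleton remodelling (percentile 93.7). Above that signal limit, the greatest falls at 18 hpi were at txlnba (3.56 at 18 hpi), tecra (chromosome 3, 45250201 to 45254400; 27.1 to 3.01), ckmt2b (chromosome 5, 50946201 to 50949000; 40.4 to 6.5), gp1bb (chromosome 8, 4528801 to 4530600; 24.4 to 3.77), gls2b (chromosome 22, 10080001 to 10082200; 35.1 to 6.06) and ldb3b (chromosome 12, 25971201 to 25974000). The gene ckmt2b encodes the mitochondrial creatine kinase of muscle, tecra an enzyme of fatty acid elongation and gls2b a glutaminase. The greatest rises above the limit were at sb:cb1058, pigrl2.3, setd1bb (chromosome 8, 34826401 to 34827000; 2.88 to 16.9), tmem163a (chromosome 9, 23442801 to 23452400; 2.97 to 17.1), ush1g (chromosome 3, 56828801 to 56829400; 5.05 to 24.2) and mafbb; setd1bb encodes an H3K4 methyltransferase. In all, 2049 regions were higher and 4114 lower than control at 18 hpi, so 33.2% of the changed regions were higher; after centring the numbers were 3027 and 3025, or 50.0%. Directly between 18 and 9 hpi, 41 regions were higher at 18 hpi and 1490 lower as deposited, with a median log2 change of −0.35, and 293 and 306 after centring.

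How many H3K27Ac regions were back near the control level at 18 hpi depended on the scaling. As deposited, of the 4238 regions higher at 9 hpi, 1305 (30.8%, 95% exact binomial interval 29.4% to 32.2%) lay within 1.5-fold of control at 18 hpi, and 1583 (37.4%) were still at least 2-fold higher. Of the 2658 regions lower at 9 hpi, 55 (2.07%, 1.56% to 2.68%) lay within 1.5-fold of control and 2207 (83.0%) were still at least 2-fold lower. After centring each time on its median, 11.5% of the higher and 11.95% of the lower regions were back. The regions higher at 9 hpi had a median log2 change of −0.57 between 18 and 9 hpi, against −0.35 over all kept regions; choosing regions for a high value at 9 hpi makes some of them lower at 18 hpi by chance alone. The regions lower at 9 hpi had −0.045. The intervals treat regions as independent and cover counting error only. Both times were compared with the same control library. Pearson's r between the log2 changes at 9 and 18 hpi was 0.86 across H3K27Ac regions, against 0.50 in simulations of unchanged libraries sharing that control, and the covariance was 0.53 against 0.064, a difference of 0.47. The 1583 regions higher at both times compare with 17.3 in the simulations and 278 for independent lists, and the 2207 lower at both with 16.6 and 351. The simulated counts may be too low. The simulations called 143 regions higher and 142 lower at 9 hpi, while 293 and 306 differed 2-fold between 18 and 9 hpi after centring, some perhaps by real change. The simulated control was given the noise estimated between 18 and 9 hpi, not its own, so a control noisier than simulated could give such an excess. The single control library cannot be split, so the part of the excess that comes from the shared control cannot be given.

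Of the H3K27Ac intervals called at 9 hpi, 78.9% overlapped a control interval by at least 1 bp, and of those at 18 hpi, 81.0% did. Across the authors' 41586 merged H3K27Ac regions, 20793 (50.0%) held an interval in all 3 libraries, 8682 (20.9%) in control only, 3601 (8.66%) at 9 and 18 hpi but not in control, and 2962 (7.12%) at 9 hpi only. A promoter lay in 61.4% of the regions present in all 3 libraries and in 18.7% of those present in control only. When an interval was required in both libraries of a contrast, an alternative chosen after seeing the data, 1713 regions were higher and 956 lower at 9 hpi, and 370 and 1272 at 18 hpi.

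**Figure D2:**
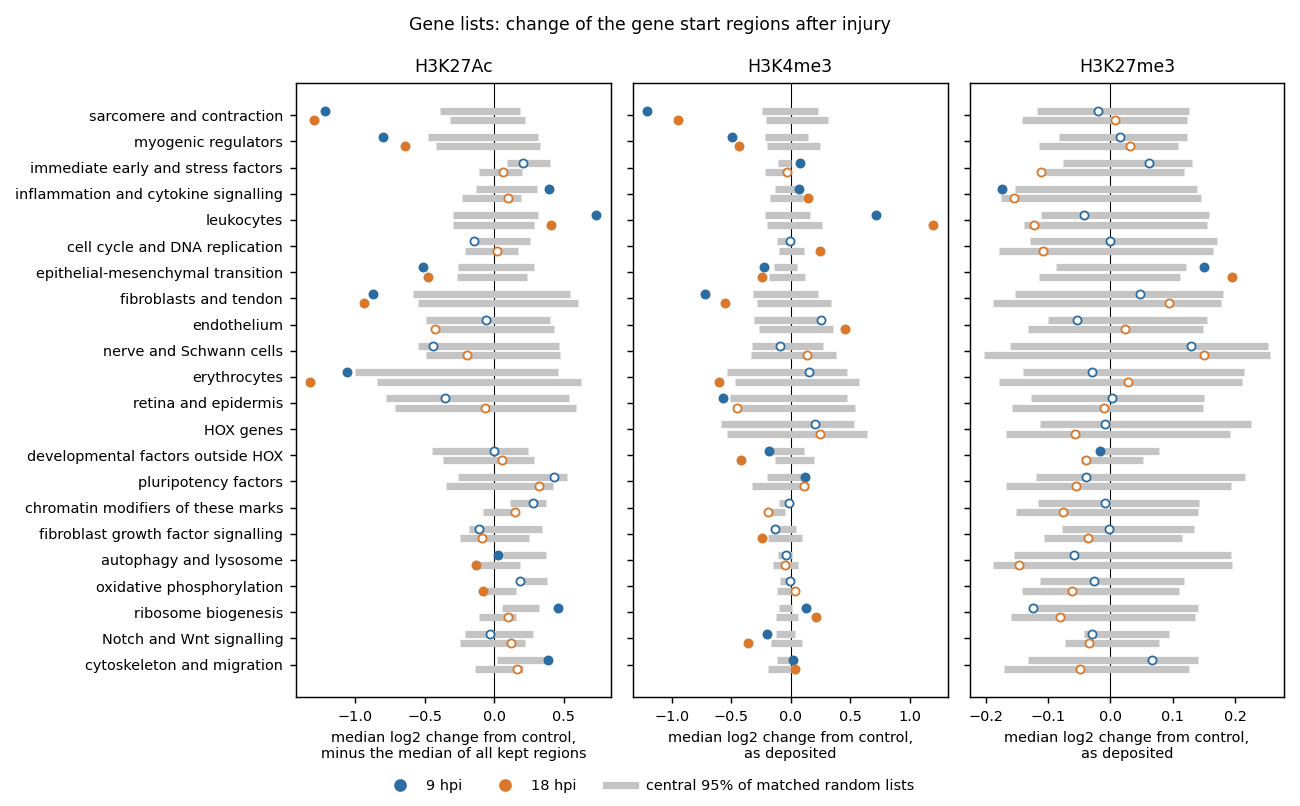
Median log2 change of the start regions of each of the 22 gene lists (vertical axis) against control for each mark, at 9 hpi (blue) and 18 hpi (orange), with the central 95% of 10000 matched random lists as grey bars; filled points lie outside that range. H3K27Ac is relative to the median of all kept regions and the other marks are as deposited; the horizontal scales differ. The sarcomere and contraction list lies left of its bars and the leukocyte list right of them in H3K27Ac and H3K4me3, with 18 hpi medians of −1.30 and 0.41 in H3K27Ac and −0.95 and 1.198 in H3K4me3.

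In H3K4me3, contractile genes were again lower and leukocyte genes higher, in libraries separate from those of H3K27Ac. The marks have the same numbers of pooled fish at each time, so a deviation of the control pool would move both alike. Of 43 sarcomere and contraction start regions, 27 were lower at 9 hpi and 20 at 18 hpi, none was higher, and the median log2 change was −1.21 and −0.95, below all random lists at both times. With the highest-signal regions the medians were −0.28 and −0.24 (percentiles 0 and 0.08). The start region of atp2a1l had an average pileup of 13.7 in control, 3.73 at 9 hpi and 3.46 at 18 hpi, ldb3b had 13.5, 5.49 and 6.39 and jph2 21.95, 8.93 and 9.47. Of 29 leukocyte start regions, 10 were higher at 9 hpi and 16 at 18 hpi, with 0 and 1 lower. Their median was 0.72 and 1.198, above all random lists at both times, and 0.31 and 0.74 with the highest-signal regions. The H3K4me3 start region of spi1b had 6.67, 17.7 and 27.2 and that of fcer1gl 2.98, 15 and 17.3. Inflammation and cytokine genes had 3 of 44 higher at 9 hpi and 8 at 18 hpi, none lower, with medians of 0.068 (percentile 99.5) and 0.14 (percentile 99.5). At 9 hpi the percentile was 75.2 within 1000 bp and 85.3 with the highest-signal regions. At il1b the values were 1.82, 6.18 and 9.48. The H3K4me3 start regions of atp2a1l, ldb3b, fcer1gl and il1b had mean signals below the filter of the counts of all regions. So did those of other genes named below, among them fosl1b, nefla, irx1b and wt1b. Myogenic regulators had 7 lower and 2 higher of 28 at 9 hpi, and 6 and 2 at 18 hpi, with medians of −0.49 (percentile 0) and −0.44 (percentile 0.01). At myod1 the H3K4me3 values were 24.8, 17.7 and 22.5, less than 2-fold apart.

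**Figure D3:**
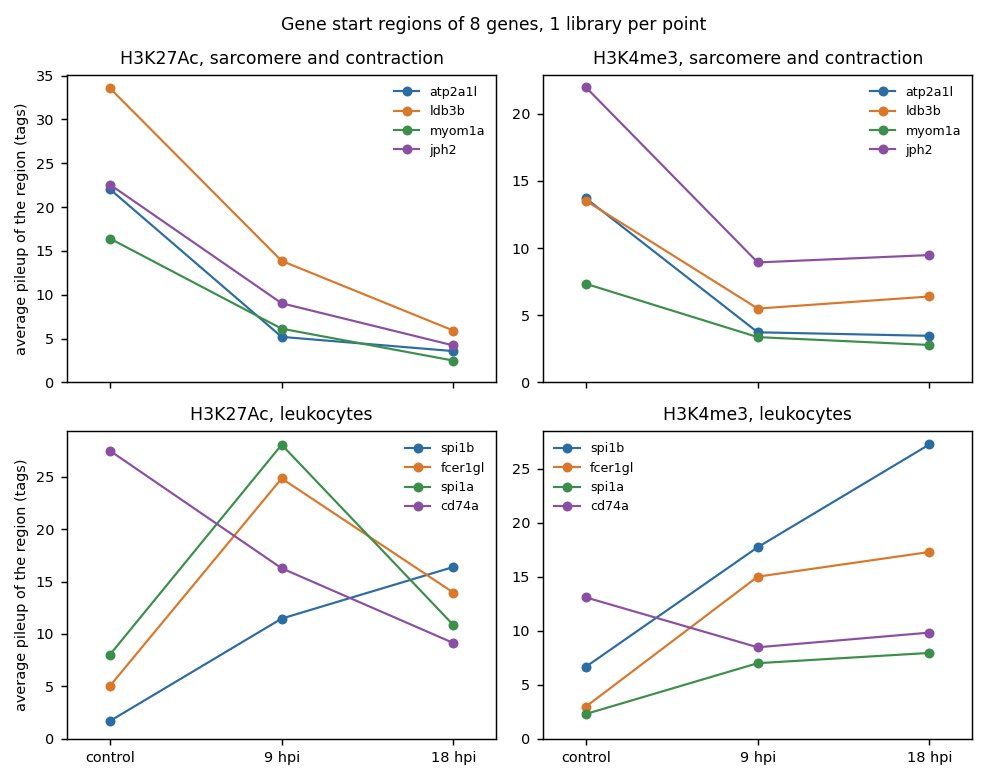
Average pileup (tags, vertical axis from 0, with a separate scale in each panel) of the region nearest the gene start in control, 9 hpi and 18 hpi, for the 4 members with the greatest H3K27Ac change of the sarcomere and contraction list (top) and of the leukocyte list (bottom), in H3K27Ac (left) and H3K4me3 (right); each point is 1 library and there are no error bars. The sarcomere genes lie below control at both later times, and spi1b, spi1a and fcer1gl lie above it, while cd74a lies below it.

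Ribosome biogenesis genes had H3K4me3 medians of 0.13 at 9 hpi and 0.21 at 18 hpi, above all random lists, although none of the 65 start regions changed 2-fold; utp20 had 26.6, 33.4 and 41.3. Cell cycle and DNA replication genes had −0.0057 at 9 hpi (percentile 85.4) and 0.24 at 18 hpi, above all random lists, with 2 of 62 higher; the kinesin genes kif23 and kif11 had 17.6, 19.4 and 35.2 and 9.86, 11.5 and 17.3 in control, at 9 hpi and at 18 hpi. Immediate early and stress factors had 0.076, above all random lists, at 9 hpi and −0.029 (percentile 94.5) at 18 hpi; fosl1b had 1.93, 8.48 and 15.3. Endothelium genes had 0.26 (percentile 97.4) and 0.46 (percentile 99.5), but percentiles of 69.8 and 84.7 at 18 hpi with regions within 1000 bp and with the highest-signal regions. Fibroblast and tendon genes had −0.72 (percentile 0.01) and −0.56 (percentile 0.08), with col6a3 at 25.9, 12.2 and 16.8; within 1000 bp the percentiles were 3.27 and 10.2. Erythrocyte genes had 0.15 (percentile 76.05) at 9 hpi and −0.60 (percentile 0.84; 4.95 within 1000 bp) at 18 hpi, with no region changed 2-fold. Nerve and Schwann cell genes had −0.09 and 0.14 (percentiles 33.1 and 73.8), while the neurofilament gene nefla had 22.8, 5.57 and 6.58. The retina and epidermis list had −0.57 and −0.45 over 7 regions (percentiles 1.65 and 3.06), and 0.023 at 9 hpi with the highest-signal regions. Within 1000 bp the percentile at 9 hpi was 41.2.

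Notch and Wnt signalling genes had H3K4me3 medians of −0.20 (percentile 0.02) and −0.36 (below all random lists), with 2 of 49 lower and 1 higher at 9 hpi and 4 and 1 at 18 hpi. The ligand genes wnt5b and wnt9a had 37.4, 12.7 and 9.72 and 24.1, 9.06 and 11.4 in control, at 9 hpi and at 18 hpi. Fibroblast growth factor signalling genes had −0.13 (percentile 3.4) and −0.25 (percentile 0.3; 3.47 with the highest-signal regions), with 10 of 41 lower at 18 hpi, among them fgf6b (27.3, 7.56 and 6.76) and fgf6a (24.8, 11.97 and 7.97), members expressed in muscle of other vertebrates. Developmental transcription factors outside the HOX clusters had −0.18 (percentile 1.34; 18.1 with the highest-signal regions) and −0.42 (below all random lists); 7 of 62 were lower and 6 higher at 9 hpi, and 8 and 1 at 18 hpi. Members moved both ways: irx1b had 20.4, 6.61 and 5.42, whereas wt1b had 2.82, 17.3 and 9.2. Epithelial-mesenchymal transition and matrix genes had −0.22 (percentile 0.05) and −0.24 (percentile 0.25), but 0.033 and 0.035, inside the random range, with regions within 1000 bp. Pluripotency factors had 0.12 (percentile 98.8) and 0.11 (percentile 94.3), and −0.032 at 9 hpi within 1000 bp; sall1a had 7.97, 21.3 and 15.3. Cytoskeleton remodelling genes had 0.016 (percentile 97.53) and 0.036 (percentile 97.95), inside the random range with the highest-signal regions and, at 18 hpi, within 1000 bp (percentile 67.3), with myh9a at 6.34, 14.2 and 20.2. Inside the range at both times were HOX genes (0.20 and 0.25, percentiles 80.4 and 75.1), chromatin modifiers (−0.011 and −0.19, percentiles 97.3 and 7.09), autophagy and lysosome (−0.039 and −0.05, percentiles 62.8 and 44.3) and oxidative phosphorylation (−0.01 and 0.033, percentiles 93.8 and 96.8). With a pseudocount of 5, the H3K4me3 changes of ldb3b, spi1b, il1b, fosl1b, myh9a and col6a3 at 9 hpi, of wnt9a and wt1b at 18 hpi and of jph2 at both times were below 2-fold.

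Among start regions at or above the median of mean signal, the greatest H3K4me3 rises at 9 hpi were at wnt2bb (chromosome 8, 27723801 to 27726200; 7.86 to 26.9), slc25a15a (chromosome 15, 3293601 to 3295000; 13.6 to 38.8), atp1a3a (chromosome 19, 6464601 to 6466800; 18.5 to 49.9), insm1a (chromosome 20, 48674601 to 48678800; 18.7 to 49.3), ccr12a (chromosome 2, 50246201 to 50252000; 11.3 to 29.4) and mfng (chromosome 22, 15251401 to 15254400; 18.7 to 43.7). At 18 hpi wnt2bb, a Wnt ligand gene, stood at 41.6, whereas insm1a was at 18.8, against 18.7 in control. The chemokine receptor gene ccr12a (37.3 at 18 hpi), slc25a15a (44.5), gmfg (chromosome 15, 46781801 to 46782400; 10.3 to 38.5), fhl3a (chromosome 16, 33701601 to 33703600; 18.1 to 50.9) and gnpda1 (chromosome 14, 23411801 to 23413400; 15.1 to 39.6) made up the rest of the greatest rises at 18 hpi. The greatest falls at 9 hpi were at pkdccb (chromosome 17, 31146001 to 31147600; 46.2 to 17.2), chst2b (chromosome 24, 5754601 to 5757600; 44.7 to 18.1), efcc1 (chromosome 11, 26427601 to 26429800; 42.2 to 17.6), ttyh1 (chromosome 16, 13913001 to 13915400; 39.03 to 16.2), vsig8a (chromosome 10, 19565601 to 19567000; 39.2 to 16.5) and trim63 (chromosome 6, 15524801 to 15526800; 53.1 to 22.8). At 18 hpi they were at fgf18a (chromosome 14, 2567401 to 2571400; 51.7 to 12.2), trim63 (16.7 at 18 hpi), sowahcb (chromosome 6, 50001 to 52600; 40.7 to 13.99), mab21l1 (chromosome 15, 33212601 to 33216600; 45.1 to 15.9), eya4 (chromosome 23, 31583401 to 31587600; 40.7 to 14.8) and fscn1b (chromosome 1, 7978001 to 7979400; 32.7 to 11.95). The gene trim63 encodes a ubiquitin ligase of muscle atrophy and eya4 a transcriptional coactivator. Over 14059 kept regions, 162 were higher and 209 lower at 9 hpi, and 272 and 257 at 18 hpi; 39 were higher and 60 lower at 18 hpi against 9 hpi. The split at 9 hpi was 43.7% higher as deposited and 52.2% after centring. Of the regions higher at 9 hpi, 22 (13.6%, 8.71% to 19.8%) were back within 1.5-fold of control at 18 hpi, and 34 of those lower (16.3%, 11.5% to 22.0%). Most 2-fold changes lay in weaker regions: among regions that held an interval whose maximum pileup was at or above the median of its list, the counts were 7 higher and 22 lower at 9 hpi, and 17 and 59 at 18 hpi. In all, 93.0% of the 9 hpi intervals and 91.8% of the 18 hpi intervals overlapped a control interval, and 15368 of 18746 merged regions (82.0%) held an interval in all 3 libraries. Pearson's r between the changes at 9 and 18 hpi was 0.72, against 0.50 simulated for unchanged libraries with a shared control, with a covariance of 0.11 against 0.035. The regions higher at both times numbered 110 (1.63 simulated, 3.13 for independent lists) and those lower at both 117 (1.67 and 3.82). As for H3K27Ac, a control library noisier than simulated could give such an excess, and its part cannot be given.

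By the 2-fold rule, H3K27me3 changed at few places, and one of them was the AP-1 gene fosl2. Its region 1352 bp into the gene (chromosome 17, 41313601 to 41316600) had an H3K27me3 average pileup of 20.3 in control, 9.12 at 9 hpi and 4.04 at 18 hpi. The same gene's start region had H3K27Ac values of 44.1, 105 and 60.1 and H3K4me3 values of 56.4, 80.1 and 82.3. Among 13590 kept regions, 115 were higher and 9 lower at 9 hpi, and 126 and 23 at 18 hpi. Between 18 and 9 hpi, 1 was higher and 5 lower at 18 hpi. The pileups include background, which limits how far a value can fall. Regions with an interval in control only, 2761 in number, had median average pileups of 7.395 in control, 5.62 at 9 hpi and 5.5 at 18 hpi. Loss of a called interval can therefore stay short of 2-fold, and the counts of lower regions may understate losses. Among start regions at or above the median of mean signal, the greatest rises at 9 hpi were at nudt6 (chromosome 14, 533601 to 536200; 4.67 to 16.6), slc2a1b (chromosome 6, 48074801 to 48107800; 5.89 to 17.7), trmt1 (chromosome 11, 30969001 to 30972000; 6.59 to 19.3), tnfrsfa (chromosome 21, 16118601 to 16121800; 4.29 to 12.6), pik3c2b (chromosome 11, 23457401 to 23459000; 4.86 to 12.2) and dbpa (chromosome 19, 10276001 to 10277400; 5.21 to 12.9). The gene slc2a1b encodes a glucose transporter, and its region was 33 kb long. At 18 hpi they were at trmt1 (25.3 at 18 hpi), a tRNA methyltransferase gene, dbpa (15.4), slc2a1b (16.6), nudt6 (12.8), slc6a8 (chromosome 8, 9080001 to 9081400; 10.1 to 26.02), the creatine transporter gene, and smad1 (chromosome 1, 35196001 to 35197400; 5.91 to 15.8). The greatest falls at 9 hpi were at pnx (chromosome 10, 2771401 to 2772400; 11.9 to 4.26) and fosl2, followed by dffb, gtf2f2b, rgl2 and armc3 with log2 changes from −0.90 to −0.79, short of 2-fold. At 18 hpi they were at fosl2, adrbk2 (chromosome 10, 44208801 to 44212000; 18.4 to 6.69), ngfrb (chromosome 12, 10000401 to 10002000; 13.7 to 5.17), itm2bb (chromosome 9, 25518201 to 25519800; 12.5 to 5.13) and prkag2a (chromosome 24, 28301201 to 28304400; 17.8 to 7.93), and dmrt1 had a log2 change of −0.99. These values are low, and with a pseudocount of 5 the changes of pnx, fosl2, tnfrsfa, pik3c2b and dbpa at 9 hpi and of ngfrb, itm2bb, prkag2a, dbpa, slc2a1b, nudt6 and smad1 at 18 hpi were below 2-fold.

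No gene list had more than 1 start region changed 2-fold in H3K27me3. Epithelial-mesenchymal transition and matrix genes had medians of 0.15 at 9 hpi (percentile 99.4) and 0.19 at 18 hpi (percentile 99.96), with 18 and 22 of 28 regions above 0; with regions within 1000 bp the percentiles were 93.7 and 95.7. Inflammation and cytokine genes had −0.17 (percentile 1.1; 9.53 within 1000 bp) and −0.15 (percentile 4.42), and 0.053 at 9 hpi with the highest-signal regions. Developmental transcription factors outside the HOX clusters, the list with the most H3K27me3 regions at 90, had −0.017 (percentile 1.69; 10.8 within 1000 bp) and −0.039 (percentile 6.08). Ribosome biogenesis at 9 hpi lay at percentile 2.5, at the limit of the random range. The other lists lay inside that range at both times: percentiles at 9 and 18 hpi were 34.97 and 61.4 for sarcomere and contraction, 47.05 and 75.8 for myogenic regulators, 16.9 and 3.78 for leukocytes and 28.5 and 24.6 for HOX genes. H3K27me3 at the starts of myom1a and jph2, for example, was 7.68, 7.91 and 6.98 and 12.5, 12.4 and 12.05. Of the regions higher at 9 hpi, 6 of 115 (5.22%, 1.94% to 11.01%) were within 1.5-fold of control at 18 hpi and 76 were still 2-fold higher; of the 9 lower regions, 3 were back. In all, 84.3% of the 9 hpi intervals and 82.0% of the 18 hpi intervals overlapped a control interval, and 9981 of 18120 merged regions (55.1%) held an interval in all 3 libraries. Pearson's r between the changes at 9 and 18 hpi was 0.82, against 0.50 simulated, with a covariance of 0.081 against 0.013. In number, 76 regions were higher and 4 lower at both times, against 0 simulated and 1.07 and 0.015 for independent lists. Here too a control library noisier than simulated could give such an excess, and its part cannot be given.

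H3K4me3 and H3K27me3 intervals often lay at the same places. In control, 6136 of 17331 H3K4me3 intervals (35.4%, 34.7% to 36.1%) overlapped an H3K27me3 interval, against 5859 of 17117 (34.2%, 33.5% to 34.9%) at 9 hpi and 5793 of 17586 (32.9%, 32.2% to 33.6%) at 18 hpi. Of 6304 places with both marks in control, 78.5% had both at 9 hpi and 77.4% at 18 hpi; 947 had lost only the H3K27me3 interval at 9 hpi and 996 at 18 hpi, while 1025 and 1067 places with both marks had not held both in control. H3K4me3 intervals with H3K27me3 had a lower median average pileup than those without, 26.4 against 33.8 in control. The tissue holds several cell types, so overlap does not show that one cell carried both marks. Among intervals whose maximum pileup was at or above the median of their list the shares were 19.3%, 17.95% and 14.9%.

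Changes of H3K27Ac and H3K4me3 at the same gene starts were correlated, with a larger coefficient at 9 hpi than at 18 hpi. Across 15751 genes, with 13538 pairs of start regions, Spearman's rho was 0.43 at 9 hpi (95% bootstrap interval over regions 0.41 to 0.44; Pearson's r 0.55) and 0.14 at 18 hpi (0.13 to 0.16; r 0.30). Genes are not independent replicates. The changes of the marks had the same sign in 55.0% of the pairs at 9 hpi and 52.2% at 18 hpi as deposited. After centring the shares were 62.3% and 51.1%. As deposited, 1529 pairs were higher and 457 lower in H3K27Ac at 9 hpi. At 18 hpi 448 were higher and 987 lower. Of the 405 pairs changed 2-fold in both marks at 9 hpi, 403 changed in the same direction, 231 higher and 172 lower, where independent changes would give 36.7 and 11.3. At 18 hpi 289 of 308 did, 108 higher and 181 lower, where independent changes would give 15.9 and 23.3. After centring both marks, 381 of 383 pairs changed in the same direction at 9 hpi, 182 of them lower. At 18 hpi 289 of 303 did, 139 of them lower. Where H3K27me3 was higher by at least 0.5 on the log2 scale, the median H3K4me3 change was −0.19 over 340 genes at 9 hpi and −0.19 over 373 genes at 18 hpi. Where it was lower by as much, the median was −0.0035 over 256 genes at 9 hpi and 0.079 over 376 genes at 18 hpi. For H3K27Ac as deposited, the medians were 0.09 at 9 hpi and −0.36 at 18 hpi where H3K27me3 was higher, and 0.46 and −0.015 where it was lower.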

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

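The tests of explanations below were chosen before the results they measure were seen, except the comparison of gene starts changed in both H3K27Ac and H3K4me3.

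The median H3K27Ac change over all kept regions was above 0 at 9 hpi (0.23 on the log2 scale) and below 0 at 18 hpi (−0.16), which is why it stands here: the same contrast with control went opposite ways at the 2 times. Each time has 1 library, and the difference was not tested. A scaling or enrichment difference between libraries that acts on all regions by their mean signal may account for these medians, since a single factor moves every region. It was set against the 2-fold changes at 9 hpi. After correction for the trend with mean signal, 76.8% of the 6896 changed regions were still changed in the same direction. The limit of under 10% for this explanation was set beforehand and was not derived from simulated libraries. The median log2 change ran from −0.17 among regions of lowest mean signal to 0.49 among those of highest, short of 2-fold. Removing such a trend could not take away most calls, so the limit could hardly have been met. A trend of that size alone does not reach 2-fold, but enrichment differences that act by region type were not tested. The size of the H3K27Ac gain or loss over all regions stays open, because the deposited values hold no depth and no spike-in of known amount.

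The leukocyte list stood above random lists in H3K27Ac at both times (percentiles 99.99 and 99.6), but at 18 hpi not with regions within 1000 bp (91.8) or with the highest-signal regions (94.2). If leukocytes entered the muscle, their genes would also gain H3K4me3, which was measured in other libraries, though of the same pooled tissue. The lower of the 2 H3K4me3 percentiles was 100, as leukocyte entry would give. A lower share of muscle cells would raise the markers of every other cell type alike only if those types kept their shares among themselves. Of the 4 lists for endothelium, fibroblasts and tendon, nerve and Schwann cells and erythrocytes, 2 lay below percentile 2.5 at 9 or 18 hpi in H3K27Ac. These were erythrocytes, and fibroblasts and tendon. With the highest-signal regions erythrocytes were at percentile 26.6 and 43.1 and only fibroblasts and tendon stayed below (1.81 and 0.34). In H3K4me3 the percentiles at 9 and 18 hpi were 0.01 and 0.08 for fibroblasts and tendon and 76.05 and 0.84 for erythrocytes. They were 97.4 and 99.5 for endothelium and 33.1 and 73.8 for nerve and Schwann cells. This argues against such an even rise as the whole cause, but a loss of other cells along with muscle was not tested. The leukocyte list was fixed beforehand and shares 0 genes with the other lists, but 26 of its 30 measured genes already had an H3K27Ac interval in control. Its members with the highest signal in control were arpc1b (average pileup 29.4 in control and 48.8 at 9 hpi), cd74a (27.5 and 16.3) and runx1 (22.4 and 64.6). Of these, cd74a went the other way from the list's median, and this 1 gene does not decide on leukocyte entry. The pools of fish have no replicate, and activation of leukocytes already present in the muscle may give the same values and was not tested.

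Many H3K27Ac regions changed alike at 9 and 18 hpi against the same control library, so a chance deviation of that library alone may account for part of them. Spearman's rho between H3K27Ac and H3K4me3 changes across gene starts, whose lower value was 0.14 at 18 hpi, lay between the bounds set beforehand and leaves this open for the regions as a whole: a deviation of the control library and a real shared change cannot be told apart there. For the gene starts changed 2-fold in both marks, at least 93.8% changed in the same direction at each time (95.4% after centring). A deviation of the H3K27Ac control library alone would give about equal numbers in both directions, which argues against it for those genes. The marks have the same numbers of pooled fish at each time, so a deviation of the control pool would move both marks alike. This comparison, chosen after the data were seen, cannot tell a deviation of the pool from a real change.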

How the results depend on the processing

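The alternatives were planned before the data were examined, except regions with an interval in both libraries, regions covering the gene start, and centring for start regions changed in both H3K27Ac and H3K4me3, which were chosen after seeing the data. No test and no paired analysis was possible because each mark and time has 1 library, so a value is said to have moved when a count changed by more than 1.5 times, or when a share or correlation left its 95% interval. Under the alternatives, 57 values stayed within these limits and 78 moved. The cause was not tested, except that a pseudocount of 5 shrinks every change, dropping the filter adds weak regions, and a choice among intervals leaves fewer regions. The depth of the libraries is unknown, so how precise the weak regions and the median shifts are cannot be given.

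As deposited, H3K27Ac had 4238 higher and 2658 lower regions at 9 hpi and 2049 and 4114 at 18 hpi. H3K4me3 had 162 and 209, then 272 and 257, and H3K27me3 had 115 and 9, then 126 and 23. The counts that moved follow. With a pseudocount of 5, H3K27Ac had 2158 higher and 1211 lower at 9 hpi, 512 higher and 2100 lower at 18 hpi; H3K4me3 had 65 higher and 97 lower at 9 hpi, 162 higher and 128 lower at 18 hpi; H3K27me3 had 28 higher and 0 lower at 9 hpi, 17 higher and 2 lower at 18 hpi. Without the filter on low values, H3K27Ac had 6003 lower at 9 hpi, 3285 higher and 7586 lower at 18 hpi; H3K4me3 had 615 higher and 769 lower at 9 hpi, 900 higher and 754 lower at 18 hpi; H3K27me3 had 31 lower at 9 hpi, 55 lower at 18 hpi. After centring on the median, H3K27Ac had 2526 higher and 4066 lower at 9 hpi. After correction for the trend with mean signal, H3K27Ac had 3124 higher at 18 hpi. With the maximum in place of the average, H3K27Ac had 7065 higher at 9 hpi; H3K27me3 had 307 higher and 28 lower at 9 hpi, 291 higher and 69 lower at 18 hpi. Among regions with an interval whose maximum was at or above the median of its list, H3K27Ac had 2406 higher and 1674 lower at 9 hpi, 774 higher and 2622 lower at 18 hpi; H3K4me3 had 7 higher and 22 lower at 9 hpi, 17 higher and 59 lower at 18 hpi; H3K27me3 had 5 lower at 9 hpi, 14 lower at 18 hpi. Among regions with an interval in both libraries, H3K27Ac had 1713 higher and 956 lower at 9 hpi, 370 higher and 1272 lower at 18 hpi; H3K4me3 had 96 higher at 9 hpi. At 9 hpi H3K27Ac had more higher than lower regions as deposited and under the alternatives run, except after centring and without the filter (5402 higher). At 18 hpi it had more lower than higher regions except after centring (3027 higher and 3025 lower) and after correction for the trend (3124 and 2933). For H3K27me3 higher regions outnumbered lower ones under each alternative run, and for H3K4me3 the majority changed with the setting.

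The share of regions changed at 9 hpi and back near control at 18 hpi also moved. As deposited it was 30.8% of higher and 2.07% of lower H3K27Ac regions. It was 11.5% and 11.95% after centring, 13.4% and 0.301% under the narrower limit given in the methods, 39.4% and 0.826% with a pseudocount of 5, and 29.01% for higher regions without the filter. For H3K4me3, with 13.6% and 16.3% as deposited, it was 5.56% and 7.18% under the narrower limit and 20% and 10.3% with a pseudocount of 5, and for H3K27me3 higher regions, with 5.22% as deposited, 0% under the narrower limit. With a pseudocount of 5 no H3K27me3 region was lower at 9 hpi, so no share could be taken. With an overlap of 50% of both intervals, the shares of 9 and 18 hpi intervals shared with control were 56.2% and 53.7% for H3K27Ac, 84.7% and 83.4% for H3K4me3, and 62.9% and 63.1% for H3K27me3. Among intervals at or above their list's median maximum they were 80.2% and 83.6%, 94.6% and 91.1%, and 83.6% for H3K27me3 at 9 hpi. H3K4me3 intervals with H3K27me3 made up 19.3%, 17.95%, 14.9% in control, at 9 hpi and at 18 hpi among those intervals, and 26.7%, 26.6%, 25.7% with an overlap of 50%. With start regions within 1000 bp, rho of the changes was 0.11 for H3K27Ac with H3K4me3 at 18 hpi, −0.14 and −0.24 for H3K27Ac with H3K27me3 at 9 and 18 hpi, and −0.19 and −0.18 for H3K4me3 with H3K27me3. Among the lists that stood apart from random lists, the median log2 change, as deposited, went to the other side of the median of the random lists in 4 cases: inflammation in H3K27me3 at 9 hpi (0.053) and retina and epidermis in H3K4me3 at 9 hpi (0.023) with the highest-signal region, and epithelial-mesenchymal transition in H3K4me3 at 9 hpi (0.033) and 18 hpi (0.035) within 1000 bp. The cause was not tested. Of the changes of the genes with the greatest rises and falls under a pseudocount of 5 and after centring, 132 kept their direction and their side of 2-fold, 12 kept their direction but were below 2-fold, all in H3K27me3 with a pseudocount of 5, and 0 changed direction. Of the 2-fold changes of the other values of the list members named, 95 were at least 2-fold and 62 below it with a pseudocount of 5, and 142 and 15 after centring, with 0 in the other direction. After centring, 11 changes that had been below 2-fold reached it.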

Other observations

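The regions nearest the starts of the paralogs spi1b and spi1a, of a myeloid transcription factor gene, differed in H3K27Ac. That of spi1b had average pileups of 1.69, 11.5 and 16.4 in control, at 9 hpi and at 18 hpi, and that of spi1a 8.02, 28.05 and 10.8. The regions are unlike: that of spi1b (chromosome 7, 32390401 to 32390800) held an interval at 18 hpi only. That of spi1a (chromosome 25, 35045201 to 35050000) held one in all 3 libraries. H3K4me3 rose at both paralogs, with 6.67, 17.7 and 27.2 at spi1b and 2.295, 6.99 and 7.94 at spi1a.

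Of 49 combinations of list, mark and time that stood apart from random lists, 49 did so after centring on the median, which cannot change a percentile, 45 with the region covering the gene start (chosen after seeing the data), 34 with the highest-signal region and 31 with regions within 1000 bp. In each of the last 2 settings, 2 of the 49 lay on the other side of the random lists' median. Combinations that stood apart only under the alternative numbered 3 with the region covering the gene start, 6 with the highest-signal region and 3 with regions within 1000 bp.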
